A study of Mus musculus with 16 samples.

How the data were processed

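Striatal RNA from 16 mouse libraries was analysed, 2 for each combination of genotype (WT or GS) and stage (intact, or 6 h, 3 d or 15 d after ATP). The labels call the replicates biological, and they were treated as separate samples. Total RNA was extracted with RNeasy kits and libraries were made with a TruSeq RNA kit, per the labels' protocols. The deposited table holds raw read counts per gene for 19457 genes, per the file headers, which give each gene an NCBI Gene ID and RefSeq transcripts. Reads were checked with FastQC 0.11.7 and the genome build was mm10, per the submitters' processing notes, and the aligner, the counter and the use of strand are not given in the sources used here. The columns name GS or NT, a stage and a number, and the NT columns were taken as WT by elimination, since the labels name WT and GS alone and each GS column matched a GS sample. The series title names LRRK2 G2019S, and GS was read as that genotype. Every gene in the table has at least 1 count in all 16 libraries, which is seen in the values and whose reason is not given, so a gene silent in any library is not analysed here. Of 373 genes in the lists, 60 are outside the table for this or another reason, including Il1b, Tnf, Il6, Ccl2, Cxcl10, S100a8, Arg1 and Xist, and this leaves the cytokine, neutrophil, monocyte and lymphocyte lists with few members. RefSeq gene positions of GRCm38.p6, which is mm10, were matched by Gene ID for 19410 of 19457 genes, and positions are 1-based.

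Total counts ran from 49220578 to 63948110 per library, mitochondrial genes took 10.3 to 13% and the 10 most abundant genes 9.73 to 12.2%. TMM factors ran from 0.947 to 1.03. Replicates differed beyond counting noise (chi-square per degree of freedom 9.75 to 32.8), so precision is set by the spread between samples more than by depth. Genes with near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt), the predicted pseudogene Gm13456, and genes that overlap others or run antisense to them are uncertain, since reads can be shared between them and strand use is not given.

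Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group, which left 18813 and removed 644, and normalised by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 16 libraries with no covariate (common biological coefficient of variation 10.1%, 8 residual degrees of freedom), and contrasts were tested with glmQLFTest and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. The 15 contrasts were injury at 3 times in each genotype, genotype at 4 stages and averaged over them, and the interaction at each time and jointly. CPM levels are TMM-normalised. Standard errors were derived as the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. The 95% intervals of fold changes come from these standard errors, so both are approximate. Of each contrast, the genes named were Lrrk2, up to 8 in each direction with the largest log2 fold change among those that passed, with a mean of at least 1 CPM and no overlap between replicates of the groups (not asked for in the interaction). For each list described they were up to 4 members with the largest change among those that passed, or the first 2 measured where fewer passed, and for genotype also genes that passed at all 4 stages. Gm13456, and genes given as levels to describe single libraries, lie outside this rule, and some genes that it names are not reported here. The 31 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, with Benjamini-Hochberg adjustment over lists within a contrast. With the estimated correlation 8 of 189 list calls were kept, 5 in WT at 3 d (pan-reactive, A1 and A2 astrocyte, complement, and infiltrating monocyte lists) and 3 in WT at 15 d (pan-reactive, A1 and complement lists). The test, the contrasts, the lists and the naming rule were chosen before the data were examined.

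The fit was tested on counts simulated from the means and spread of the real libraries, with 200 genes changed among 18813. For WT injury at 6 h edgeR recovered 60% of genes changed 1.5-fold, 76% of 2-fold, 96% of 3-fold and 98% of 4-fold changes (50 genes each), with 10 false calls, and DESeq2 made 30. For genotype at 3 d edgeR recovered 60%, 88%, 88% and 100%, with 10 false calls against 20 for DESeq2. For genotype averaged over stages it recovered 94%, 100%, 100% and 100%, with 15 false calls against 36. With fewer than 200 true changes the adjustment is stricter, so these rates may overstate recovery between genotypes. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no or a stricter filter, only the groups of each contrast, the replicate number as a block, a fold threshold, each library left out, and the average without genes near Lrrk2. A cortical marker covariate, the mean log2 CPM of the cortical list, was added after seeing the data. So was a fit without the 3 WT libraries highest in it (WT intact replicate 1, WT 6 h replicate 2 and WT 15 d replicate 1). That fit left 1 library in each of these groups. Agreement between the genotypes' responses used Pearson and Spearman correlation across genes and the overlap of calls.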

Results

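RNA was sequenced from the striatum of wild-type (WT) mice and of mice labelled GS, read here as carriers of the G2019S change in LRRK2 that the series title names. The tissue came from intact brains, or from brains collected 6 h, 3 d or 15 d after a unilateral striatal injection of 0.8 µl of 500 mM ATP, a molecule that damaged cells release. Genotype and stage made 8 groups of 2 libraries each, 16 in all. Replicate libraries correlated at a Pearson r of 0.990 to 0.994 across genes on the log2 CPM scale, and genes are not independent replicates. The first principal component held 52.3% of the variance. The injury comparisons set each injected group against intact striatum of the same genotype, so the needle track, the injected volume and ATP itself all enter them. Of 19457 genes, 18813 were tested. Values written as a ± b are edgeR log2 fold changes with standard errors derived from the F statistic (2 libraries per group). Where a level in CPM (read counts scaled to library size) is named, they are mean ± SD, n = 2.

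Lrrk2 is the mouse gene of the kinase named in the series title, which phosphorylates Rab proteins (NCBI Gene 66725, mm10 chromosome 15, positions 91672791 to 91816124). Its level was 149 ± 19.8 CPM in WT and 193 ± 35.1 CPM in GS intact striatum, 135 ± 0.202 and 136 ± 1.09 CPM at 6 h, 182 ± 36.5 and 175 ± 4.77 CPM at 3 d, and 111 ± 1.7 and 118 ± 7.2 CPM at 15 d (SD, n = 2 each). Whether GS mice carry the change in this gene or in an added copy is not given in the sources used here, and a change of a single residue need not alter the level, so these values check no genotype label. In GS, Lrrk2 fell at 6 h (-0.51 ± 0.13, edgeR adjusted p = 0.018) and at 15 d (-0.71 ± 0.13, edgeR adjusted p = 0.000665). In WT it fell at 15 d (-0.42 ± 0.13, edgeR adjusted p = 0.027). It did not pass in WT at 6 h (-0.14 ± 0.13) or 3 d (0.29 ± 0.13), or in GS at 3 d (-0.14 ± 0.13). Between genotypes it passed at no stage, with 0.37 ± 0.13 in intact striatum, 0.00080 ± 0.13 at 6 h, -0.06 ± 0.13 at 3 d and 0.08 ± 0.13 at 15 d (GS minus WT). The GS response minus the WT response was -0.37 ± 0.18 at 6 h, -0.44 ± 0.18 at 3 d and -0.29 ± 0.18 at 15 d, none of which passed in edgeR (adjusted p = 0.549, 0.469 and 0.909). The call in GS at 6 h was lost without GS intact replicate 2 (-0.32, adjusted p = 0.209), GS 6 h replicate 1 (-0.50, adjusted p = 0.104) or GS 6 h replicate 2 (-0.52, adjusted p = 0.0926) in edgeR. The call in WT at 15 d was lost without WT intact replicate 2 (-0.28, adjusted p = 0.217), WT 15 d replicate 1 (-0.44, adjusted p = 0.0709) or WT 15 d replicate 2 (-0.41, adjusted p = 0.129), and WT at 3 d passed without WT 3 d replicate 2 (0.48, adjusted p = 0.0182).

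**Figure D1:**
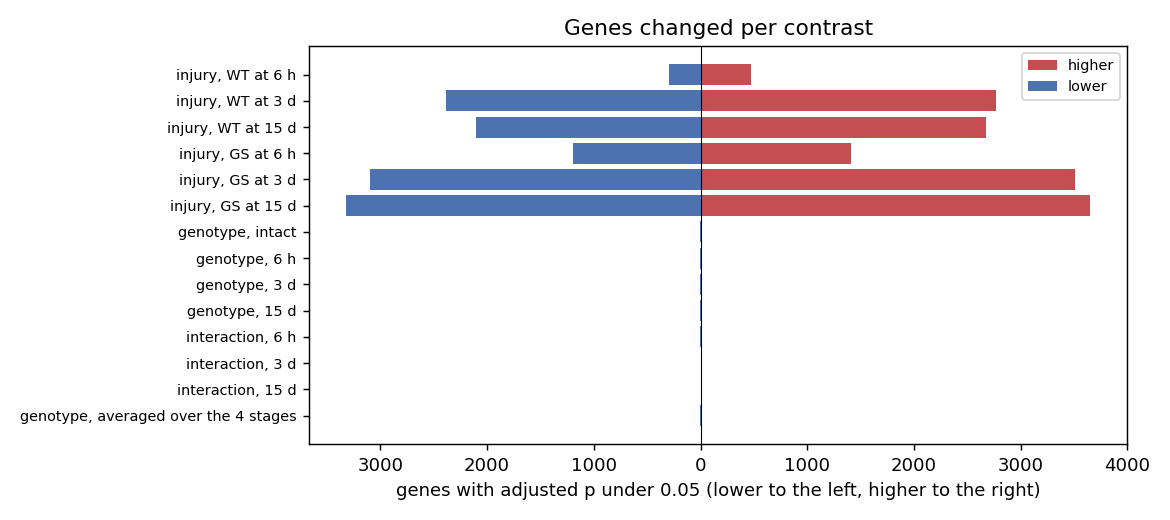
Number of genes with an edgeR adjusted p under 0.05 in each contrast (horizontal axis), with higher genes to the right of 0 and lower genes to the left. Injury contrasts hold 769 to 6972 genes and contrasts between genotypes hold 0 to 3.

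At 6 h in WT, C5ar1, the receptor of complement fragment C5a, rose by 4.54 ± 0.59, and C3ar1 (2.25 ± 0.52), Il1a (2.18 ± 0.35) and the interleukin-1 receptor antagonist gene Il1rn (3.77 ± 0.95) rose with it. So did the niacin receptor gene Hcar2 (3.44 ± 0.60) and the cholesterol hydroxylase gene Ch25h (3.07 ± 0.52). Among cytokines and chemokines 2 of 4 measured members rose (3 adjusted over the list alone). The cytokine and chemokine list had a camera adjusted p = 8.88e-05 (adjusted p = 0.15 with an estimated correlation). For complement and integrin receptors, 2 of 10 measured members rose (4 adjusted over the list alone, where 1 fell). The complement and integrin list had a camera adjusted p = 0.00323 (adjusted p = 0.57 with an estimated correlation). In the A2 astrocyte set 4 of 8 measured members rose (4 adjusted over the list alone), including Cd109 (2.94 ± 0.59), Cd14 (2.59 ± 0.33), Sphk1 (2.15 ± 0.57) and Emp1 (1.66 ± 0.42). The A2 astrocyte list had a camera adjusted p = 1.52e-06 (adjusted p = 0.15 with an estimated correlation). Of the pan-reactive astrocyte genes, 2 of 10 measured members rose (2 adjusted over the list alone), among them the intermediate filament gene Gfap (1.47 ± 0.22) and the oncostatin M receptor gene Osmr (1.51 ± 0.28). The pan-reactive astrocyte list had a camera adjusted p = 0.00287 (adjusted p = 0.57 with an estimated correlation). The heat shock and stress list held the cell cycle inhibitor gene Cdkn1a (1.98 ± 0.17), the haem oxygenase gene Hmox1 (2.40 ± 0.50) and Trib3 (1.49 ± 0.27), and 4 of 12 measured members rose (4 adjusted over the list alone). The heat shock and stress list had a camera adjusted p = 1.63e-05 (adjusted p = 0.15 with an estimated correlation).

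Of the homeostatic microglia genes in WT at 6 h, 3 of 11 measured members fell (9 adjusted over the list alone), with Olfml3 (-1.19 ± 0.22), Siglech (-0.73 ± 0.16) and the ADP receptor gene P2ry12 (-0.69 ± 0.18). The homeostatic microglia list had a camera adjusted p = 5e-09 (adjusted p = 0.35 with an estimated correlation). Among immediate early genes 2 of 15 measured members rose and 5 fell (4 and 7 adjusted over the list alone), with Nr4a1 (-1.85 ± 0.33), Egr2 (-1.71 ± 0.34) and Arc (-1.52 ± 0.28) lower and Maff (1.92 ± 0.45) higher. The immediate early list had a camera adjusted p = 0.0237 (adjusted p = 0.61 with an estimated correlation). The neurofilament gene Nefm (-0.80 ± 0.12), the organic anion transporter gene Slc22a8 (-1.61 ± 0.23) and Npas1 (-1.72 ± 0.44) fell. Cell cycle genes included Mki67 (2.09 ± 0.50) and Bub1 (2.40 ± 0.56), and 4 of 14 measured members rose (8 adjusted over the list alone). The cell cycle list had a camera adjusted p = 3.45e-08 (adjusted p = 0.45 with an estimated correlation). Haemoglobin transcripts rose too, with Hba-a1 (4.09 ± 0.55), Hba-a2 (4.26 ± 0.60), Hbb-bs (3.48 ± 0.56) and Hbb-bt (3.63 ± 0.56), which share reads between near-identical copies and so are uncertain one by one. In the erythrocyte list 4 of 4 measured members rose (4 adjusted over the list alone). The erythrocyte list had a camera adjusted p = 1.59e-11 (adjusted p = 0.15 with an estimated correlation). In total 769 of 18813 genes changed in edgeR, 477 up and 292 down, of which 89 rose and 66 fell by at least 2-fold. That number was 1457 with DESeq2, 1482 with only these groups fitted, and 85, 270, 218 and 63 without WT intact replicate 1, WT intact replicate 2, WT 6 h replicate 1 and WT 6 h replicate 2. C5ar1, Hba-a1, Hba-a2, Cd14, Cdkn1a and Nefm passed without each of the 16 libraries, 25 other genes named in this comparison lost their call without some library, and the cortical marker Slc17a7 differed between replicates (136 and 15.6 CPM intact, 17.2 and 72.7 CPM at 6 h). Of the 31 named calls, 15 were lost with limma-voom, 5 with no low-count filter, 1 with DESeq2 and 1 with the cortical marker score as a covariate. Nearly all were lost without the 3 WT libraries highest in cortical markers (WT intact replicate 1, WT 6 h replicate 2 and WT 15 d replicate 1). That fit left 1 library on each side of this comparison, so the loss cannot be assigned to cortical tissue.

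In GS at 6 h Socs3, a suppressor of cytokine signalling, rose by 3.12 ± 0.33, with Hcar2 (3.70 ± 0.62), Il1rn (3.19 ± 0.91), Il1a (1.62 ± 0.37), C3ar1 (2.94 ± 0.52) and C5ar1 (2.76 ± 0.49). Of the cytokines and chemokines, 4 of 4 measured members rose (4 adjusted over the list alone). For cytokine and chemokine genes, camera gave adjusted p = 0.0018 (adjusted p = 0.4 with an estimated correlation). For the A2 astrocyte set, 5 of 8 measured members rose (6 adjusted over the list alone), with Cd109 (3.46 ± 0.55) and Cd14 (2.79 ± 0.33). For A2 astrocyte genes, camera gave adjusted p = 8.67e-06 (adjusted p = 0.4 with an estimated correlation). The pan-reactive astrocyte list gave Gfap (1.96 ± 0.22) and Osmr (1.65 ± 0.28), and 3 of 10 measured members rose (4 adjusted over the list alone). For pan-reactive astrocyte genes, camera gave adjusted p = 0.0018 (adjusted p = 0.57 with an estimated correlation). Cdkn1a rose by 2.43 ± 0.17 (edgeR adjusted p = 6.71e-06), and of the heat shock and stress genes 3 of 12 measured members rose and 3 fell (3 and 3 adjusted over the list alone). For heat shock and stress genes, camera gave adjusted p = 0.172 (adjusted p = 0.71 with an estimated correlation). Immediate early genes went both ways, with Maff (2.27 ± 0.41) and Fosb (2.02 ± 0.35) higher and Egr2 (-1.79 ± 0.35) lower, and 4 of 15 measured members rose and 4 fell (4 and 4 adjusted over the list alone). For immediate early genes, camera gave adjusted p = 0.934 (adjusted p = 0.98 with an estimated correlation). In the erythrocyte list 4 of 4 measured members rose (4 adjusted over the list alone), with Hbb-bt (3.10 ± 0.55) and Hba-a2 (3.02 ± 0.56), both uncertain for reads shared with near-identical copies. For erythrocyte genes, camera gave adjusted p = 1.98e-05 (adjusted p = 0.4 with an estimated correlation). Dnah12 (3.60 ± 0.57), an axonemal dynein gene, rose, while the choroid plexus and ependyma list, in which 3 of 11 measured members rose (6 adjusted over the list alone), moved in libraries whose level of the choroid plexus gene Ttr was 359 and 56.9 CPM intact and 34.4 and 192 CPM at 6 h. The choroid plexus and ependyma list had a camera adjusted p = 0.0389 (adjusted p = 0.71 with an estimated correlation).

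In the endothelium list in GS at 6 h, 8 of 11 measured members fell (8 adjusted over the list alone), including the receptor kinase genes Tek (-1.58 ± 0.28) and Kdr (-1.33 ± 0.23) and the efflux pump gene Abcb1a (-0.89 ± 0.17). The endothelium list had a camera adjusted p = 2.59e-06 (adjusted p = 0.4 with an estimated correlation). The amino acid transporter gene Slc38a5 (-3.04 ± 0.36) and the chemokine gene Cxcl12 (-1.90 ± 0.21) were lower as well. Of the striatal projection neuron genes, 1 of 18 measured members rose and 8 fell (1 and 9 adjusted over the list alone), with the adenosine receptor gene Adora2a (-0.70 ± 0.086) and the dopamine receptor gene Drd2 (-0.51 ± 0.098) lower and Pdyn (0.94 ± 0.15), which encodes prodynorphin, higher. The projection neuron list had a camera adjusted p = 7.02e-05 (adjusted p = 0.62 with an estimated correlation). Homeostatic microglia included Olfml3 (-1.36 ± 0.21), P2ry12 (-0.99 ± 0.18) and Selplg (-0.80 ± 0.19), and 6 of 11 measured members fell (9 adjusted over the list alone). For homeostatic microglia genes, camera gave adjusted p = 7.11e-07 (adjusted p = 0.44 with an estimated correlation). Nefm (-1.0 ± 0.12) fell. Of the enzymes that break down extracellular nucleotides, Nt5e (1.12 ± 0.17) rose and Entpd1 (-0.63 ± 0.12) fell, and in their list 2 of 14 measured members rose and 3 fell (3 and 5 adjusted over the list alone). The purinergic list had a camera adjusted p = 0.427 (adjusted p = 0.71 with an estimated correlation). In total 2605 genes changed in edgeR, 1406 up and 1199 down, of which 393 rose and 163 fell by at least 2-fold. Without GS intact replicate 1, GS intact replicate 2, GS 6 h replicate 1 or GS 6 h replicate 2 that number was 1465, 866, 936 or 1062, and 7 of the 32 genes named in this comparison (Lrrk2, Il1rn, Il1a, Egr2, Selplg, Drd2 and Entpd1) lost their call without some library, with edgeR adjusted p up to 0.209. With limma-voom the calls of Il1rn and C3ar1 were lost (adjusted p = 0.189 and 0.0688), and that of Il1rn without the 3 WT libraries (edgeR adjusted p = 0.0565).

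At 3 d in WT, Spp1, which encodes osteopontin, rose by 9.95 ± 0.78 from 0.54 ± 0.511 to 528 ± 307 CPM (SD, n = 2 each), and the scavenger receptor gene Msr1 (8.01 ± 0.58), Il1rn (6.22 ± 0.88), C5ar1 (5.55 ± 0.58) and Ms4a6c (5.38 ± 0.38) rose with it. In the phagocytic microglia list 12 of 14 measured members rose (12 adjusted over the list alone, where 1 fell), with the galectin gene Lgals3 (4.78 ± 0.54) and Cd68 (2.72 ± 0.33). The phagocytic microglia list had a camera adjusted p = 7.64e-13 (adjusted p = 0.12 with an estimated correlation). Homeostatic microglia genes, lower at 6 h, were higher: 10 of 11 measured members rose (10 adjusted over the list alone), with Fcrls (2.69 ± 0.36), Olfml3 (1.62 ± 0.20) and Gpr34 (1.24 ± 0.23). Camera on the homeostatic microglia list gave adjusted p = 6.67e-09 (adjusted p = 0.13 with an estimated correlation). Infiltrating monocyte and macrophage markers included Thbs1 (5.12 ± 0.66) and the lysozyme gene Lyz2 (4.45 ± 0.49), and 4 of 4 measured members rose (4 adjusted over the list alone). The monocyte and macrophage list had a camera adjusted p = 1.52e-06 (adjusted p = 0.029 with an estimated correlation). Of the complement and integrin receptor genes, 10 of 10 measured members rose (10 adjusted over the list alone), with C3 (8.38 ± 1.27). For complement and integrin genes, camera gave adjusted p = 1.16e-23 (adjusted p = 0.019 with an estimated correlation). For cell cycle genes, 14 of 14 measured members rose (14 adjusted over the list alone), with Cdk1 (5.77 ± 0.62), Bub1 (5.18 ± 0.50), Ccnb1 (4.65 ± 0.54) and Mki67 (4.59 ± 0.49). For cell cycle genes, camera gave adjusted p = 1.05e-19 (adjusted p = 0.079 with an estimated correlation).

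Gfap rose in WT at 3 d by 5.08 ± 0.25, from 30 ± 3.95 to 1010 ± 158 CPM (SD, n = 2 each), beside Lcn2 (4.65 ± 0.69), Vim (4.43 ± 0.35) and Osmr (2.66 ± 0.28), and among pan-reactive astrocyte genes 10 of 10 measured members rose (10 adjusted over the list alone). Camera on the pan-reactive astrocyte list gave adjusted p = 1.9e-22 (adjusted p = 0.019 with an estimated correlation). In the A1 set 8 of 11 and in the A2 set 8 of 8 measured members rose (8 and 8 adjusted over the list alone). Camera gave adjusted p = 3.39e-09 for A1 and 6.97e-12 for A2 (adjusted p = 0.019 and 0.029 with an estimated correlation). The RNA came from striatal tissue, so no list's rise can be assigned to the cell type that names it. For the interferon response, 10 of 10 measured members rose (10 adjusted over the list alone), with Ifi27l2a (4.02 ± 0.74), Irf7 (3.82 ± 0.63), Isg15 (3.38 ± 0.49) and Oasl2 (3.24 ± 0.42). The interferon list had a camera adjusted p = 8.96e-11 (adjusted p = 0.11 with an estimated correlation). Of the immediate early genes, 12 of 15 measured members rose (14 adjusted over the list alone), led by Atf3 (4.43 ± 0.56). Camera on the immediate early list gave adjusted p = 5.03e-09 (adjusted p = 0.12 with an estimated correlation). Heat shock and stress genes held Hmox1 (3.39 ± 0.51), and 6 of 12 measured members rose (7 adjusted over the list alone). Camera on the heat shock and stress list gave adjusted p = 1.38e-05 (adjusted p = 0.078 with an estimated correlation). The nucleotide receptor genes P2ry2 (2.43 ± 0.45) and P2ry6 (2.35 ± 0.24) rose, and in the purinergic list 5 of 14 measured members rose and 1 fell (6 and 1 adjusted over the list alone). For purinergic genes, camera gave adjusted p = 0.0143 (adjusted p = 0.13 with an estimated correlation).

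In the cholesterol synthesis list in WT at 3 d, 1 of 14 measured members rose and 8 fell (1 and 12 adjusted over the list alone), with Insig1 (-0.76 ± 0.087). The cholesterol list had a camera adjusted p = 1.52e-06 (adjusted p = 0.11 with an estimated correlation). Of the striatal projection neuron genes, 1 of 18 measured members rose and 4 fell (1 and 4 adjusted over the list alone), with Adora2a (-0.42 ± 0.086) and the adenylyl cyclase gene Adcy5 (-0.38 ± 0.075). For projection neuron genes, camera gave adjusted p = 0.0278 (adjusted p = 0.49 with an estimated correlation). Cortical excitatory neuron genes fell, with Slc17a7 (-3.50 ± 0.88), Neurod2 (-3.47 ± 0.92), Tbr1 (-2.73 ± 0.84) and, outside the list, Rtn4rl2 (-4.12 ± 0.88), and 5 of 9 measured members fell (6 adjusted over the list alone). The cortical neuron list had a camera adjusted p = 0.0426 (adjusted p = 0.4 with an estimated correlation). These cortical markers were unequal between the intact replicates, with Slc17a7 at 136 and 15.6 CPM. Without WT intact replicate 1 the calls of Slc17a7 (-1.22, adjusted p = 0.315), Neurod2 (-1.80, adjusted p = 0.236), Tbr1 (-1.08, adjusted p = 0.451) and Rtn4rl2 (-2.56, adjusted p = 0.0681) were lost in edgeR. In total 5153 genes changed in edgeR, 2771 up and 2382 down, of which 1021 rose and 396 fell by at least 2-fold. That number was 2414 without WT intact replicate 1, 3209 without WT 3 d replicate 2, 3216 with only these groups fitted, 2467 with the cortical marker score as a covariate and 2178 without the 3 WT libraries highest in cortical markers. Without WT 3 d replicate 2 the calls of Slc17a7 (-3.24, adjusted p = 0.0706), Neurod2 (-3.53, adjusted p = 0.0689) and Tbr1 (-2.26, adjusted p = 0.158) were lost, and without WT 3 d replicate 1 that of Neurod2 (-3.41, adjusted p = 0.0607). With limma-voom those of C3, Slc17a7, Neurod2 and Tbr1 were lost. With the covariate or without the 3 WT libraries those of Slc17a7, Neurod2 and Tbr1 were lost. These genes are members of the list that defines both settings, so that loss is no separate check of them. With only these groups fitted that of Tbr1 was lost.

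In GS at 3 d Spp1 rose by 10.68 ± 0.78, from 0.675 ± 0.109 to 1110 ± 422 CPM (SD, n = 2 each), with Msr1 (8.27 ± 0.56), Lgals3 (5.91 ± 0.57), C3ar1 (5.77 ± 0.51), Lyz2 (5.50 ± 0.49) and the sialoadhesin gene Siglec1 (5.50 ± 0.61). Of the phagocytic microglia genes, 12 of 14 measured members rose and 1 fell (12 and 1 adjusted over the list alone). For phagocytic microglia genes, camera gave adjusted p = 1.21e-13 (adjusted p = 0.12 with an estimated correlation). Homeostatic microglia genes included Fcrls (3.11 ± 0.36), and 11 of 11 measured members rose (11 adjusted over the list alone). The homeostatic microglia list had a camera adjusted p = 1.99e-13 (adjusted p = 0.11 with an estimated correlation). Dividing-cell genes rose, with Mki67 (5.41 ± 0.51), Cdk1 (5.40 ± 0.58) and Top2a (5.28 ± 0.49), and for the cell cycle list 14 of 14 measured members rose (14 adjusted over the list alone). Camera on the cell cycle list gave adjusted p = 6.24e-19 (adjusted p = 0.076 with an estimated correlation). Gfap rose by 5.35 ± 0.25 and Vim (4.54 ± 0.35) with it, and for pan-reactive astrocyte genes 10 of 10 measured members rose (10 adjusted over the list alone). The pan-reactive astrocyte list had a camera adjusted p = 4.83e-15 (adjusted p = 0.06 with an estimated correlation). In the interferon list 10 of 10 measured members rose (10 adjusted over the list alone), with Ifi27l2a (4.98 ± 0.77), Ifit1 (4.15 ± 0.39) and Irf7 (3.85 ± 0.59). For interferon genes, camera gave adjusted p = 1.73e-12 (adjusted p = 0.076 with an estimated correlation). Atf3 (4.19 ± 0.53) led the immediate early genes, of which 8 of 15 measured members rose (12 adjusted over the list alone). The immediate early list had a camera adjusted p = 0.000143 (adjusted p = 0.28 with an estimated correlation). The matrix gene Tnc (3.76 ± 0.35) rose, and in the fibroblast and extracellular matrix list 7 of 11 measured members rose (8 adjusted over the list alone, where 1 fell). The fibroblast and matrix list had a camera adjusted p = 2e-04 (adjusted p = 0.22 with an estimated correlation).

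In the striatal projection neuron list in GS at 3 d, 1 of 18 measured members rose and 14 fell (1 and 15 adjusted over the list alone), with Adora2a (-0.83 ± 0.086), Adcy5 (-0.72 ± 0.075) and Ppp1r1b (-0.66 ± 0.10), which encodes a regulator of protein phosphatase, lower and Pdyn (0.62 ± 0.15) higher. Camera on the projection neuron list gave adjusted p = 1.18e-08 (adjusted p = 0.21 with an estimated correlation). Of the general neuronal and synaptic genes, 8 of 14 measured members fell (10 adjusted over the list alone), with Nefm (-0.92 ± 0.12) and Rbfox3 (-0.73 ± 0.097). The general neuronal list had a camera adjusted p = 0.000106 (adjusted p = 0.22 with an estimated correlation). Cholesterol synthesis genes included Insig1 (-0.67 ± 0.087), and 1 of 14 measured members rose and 8 fell (1 and 10 adjusted over the list alone). For cholesterol genes, camera gave adjusted p = 0.000372 (adjusted p = 0.21 with an estimated correlation). Ffar3 (-2.17 ± 0.35), Gjd3 (-1.97 ± 0.38) and Fgf16 (-1.91 ± 0.33) were among the genes that fell most. The nucleotide receptor genes P2ry2 (2.70 ± 0.42) and P2ry6 (2.48 ± 0.24) rose, and 5 of 14 measured members rose and 3 fell (6 and 4 adjusted over the list alone). Camera on the purinergic list gave adjusted p = 0.122 (adjusted p = 0.31 with an estimated correlation). In total 6598 genes changed in edgeR, 3505 up and 3093 down, of which 1315 rose and 297 fell by at least 2-fold. That number was 3928 without GS 3 d replicate 2, and Pdyn lost its call without GS intact replicate 2 (0.50, adjusted p = 0.0601) or GS 3 d replicate 1 (0.40, adjusted p = 0.0645).

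At 15 d in WT, Cd74, the invariant chain of MHC class II, rose by 5.86 ± 0.51, from 1.09 ± 0.696 to 64.2 ± 34.9 CPM (SD, n = 2 each), with H2-Aa (5.11 ± 0.53) and H2-Ab1 (4.20 ± 0.41), and in the MHC class II list 4 of 5 measured members rose (4 adjusted over the list alone). The MHC class II list had a camera adjusted p = 1.29e-07 (adjusted p = 0.067 with an estimated correlation). Spp1 (8.84 ± 0.77), C3 (8.41 ± 1.27), Lyz2 (6.38 ± 0.51), Cd52 (5.21 ± 0.34) and the apolipoprotein gene Apoc1 (5.20 ± 0.47) rose too. Of the phagocytic microglia genes, 13 of 14 measured members rose (13 adjusted over the list alone), with the receptor gene Trem2 (3.38 ± 0.34) and its adaptor gene Tyrobp (3.64 ± 0.30). Camera on the phagocytic microglia list gave adjusted p = 2.21e-23 (adjusted p = 0.067 with an estimated correlation). Homeostatic microglia included Fcrls (3.04 ± 0.36), and 10 of 11 measured members rose (11 adjusted over the list alone). For homeostatic microglia genes, camera gave adjusted p = 3.62e-10 (adjusted p = 0.16 with an estimated correlation). For pan-reactive astrocyte genes, 9 of 10 measured members rose (9 adjusted over the list alone), with Gfap (4.95 ± 0.25) and Vim (4.35 ± 0.35). For pan-reactive astrocyte genes, camera gave adjusted p = 7.28e-22 (adjusted p = 0.027 with an estimated correlation). In the A1 astrocyte set 8 of 11 measured members rose (8 adjusted over the list alone, where 2 fell), with Psmb8 (3.15 ± 0.35) and Serping1 (3.05 ± 0.27), and Cd109 (5.71 ± 0.54) rose in the A2 set. For A1 astrocyte genes, camera gave adjusted p = 2.87e-10 (adjusted p = 0.027 with an estimated correlation). Interferon genes held Irf7 (3.31 ± 0.63) and Ifit1 (3.15 ± 0.38), and 10 of 10 measured members rose (10 adjusted over the list alone). Camera on the interferon list gave adjusted p = 9.11e-13 (adjusted p = 0.068 with an estimated correlation). Complement and integrin receptor genes moved likewise: 9 of 10 measured members rose (10 adjusted over the list alone). Camera on the complement and integrin list gave adjusted p = 1.59e-23 (adjusted p = 0.027 with an estimated correlation).

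In the fibroblast and matrix list in WT at 15 d, 7 of 11 measured members rose (7 adjusted over the list alone, where 1 fell), with the collagen gene Col3a1 (2.05 ± 0.38) and the crosslinking enzyme gene Lox (4.38 ± 0.42). For fibroblast and matrix genes, camera gave adjusted p = 5.48e-05 (adjusted p = 0.18 with an estimated correlation). Of the myelin and oligodendrocyte genes, 4 of 14 measured members rose (7 adjusted over the list alone), with Mbp (0.51 ± 0.098). The myelin list had a camera adjusted p = 0.00695 (adjusted p = 0.4 with an estimated correlation). Cilia genes Ccdc153 (3.40 ± 0.71) and Foxj1 (2.58 ± 0.27) rose within the choroid plexus and ependyma list, in which 7 of 11 measured members rose (9 adjusted over the list alone). For choroid plexus and ependyma genes, camera gave adjusted p = 1.48e-06 (adjusted p = 0.16 with an estimated correlation). Among striatal projection neuron genes 11 of 18 measured members fell (12 adjusted over the list alone), with the enkephalin precursor gene Penk (-0.48 ± 0.11) and Adora2a (-0.46 ± 0.086). The projection neuron list had a camera adjusted p = 9.42e-07 (adjusted p = 0.23 with an estimated correlation). For general neuronal genes, 11 of 14 measured members fell (13 adjusted over the list alone), with Nefm (-0.60 ± 0.12) and Syn1 (-0.49 ± 0.082). For general neuronal genes, camera gave adjusted p = 1.48e-06 (adjusted p = 0.16 with an estimated correlation). Of the Lrrk2-associated Rab and lysosome genes, 6 of 14 measured members rose (6 adjusted over the list alone), with Rab29 (1.09 ± 0.27) and the cathepsin gene Ctsl (1.18 ± 0.20). The Rab and lysosome list had a camera adjusted p = 0.0127 (adjusted p = 0.23 with an estimated correlation). Gjd3 (-1.65 ± 0.38) and the neuropeptide gene Vip (-1.79 ± 0.55) fell. In total 4779 genes changed in edgeR, 2672 up and 2107 down, of which 1123 rose and 238 fell by at least 2-fold. That number was 2444 without WT intact replicate 1, 2264 without WT 15 d replicate 2 and 2281 without the 3 WT libraries highest in cortical markers, and Rab29, Vip and Gjd3 lost their calls without WT intact replicate 1 (adjusted p = 0.102, 0.808 and 0.0681) or WT 15 d replicate 2 (adjusted p = 0.0934, 0.152 and 0.0701). The calls of Penk without WT intact replicate 2 (adjusted p = 0.0562) and of Vip without WT 15 d replicate 1 (adjusted p = 0.0855) were lost as well. Those of C3 and Vip were lost with limma-voom, that of Vip with only these groups fitted or the cortical covariate, and those of Lrrk2, Rab29, Vip and Gjd3 without the 3 WT libraries.

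In GS at 15 d Spp1 (9.40 ± 0.76), C3 (7.71 ± 1.13), Lyz2 (7.28 ± 0.52), Msr1 (5.85 ± 0.59), Cd109 (5.79 ± 0.53), Apoc1 (5.55 ± 0.47) and Cd52 (5.46 ± 0.34) rose. Of the phagocytic microglia genes, 13 of 14 measured members rose (13 adjusted over the list alone), with Tyrobp (4.41 ± 0.31) and Trem2 (4.04 ± 0.34). The phagocytic microglia list had a camera adjusted p = 3.41e-21 (adjusted p = 0.095 with an estimated correlation). Homeostatic microglia genes included Fcrls (3.78 ± 0.36), and 11 of 11 measured members rose (11 adjusted over the list alone). Camera on the homeostatic microglia list gave adjusted p = 7.55e-12 (adjusted p = 0.15 with an estimated correlation). In the MHC class II list 4 of 5 measured members rose (4 adjusted over the list alone), with Cd74 (5.13 ± 0.50) and H2-Aa (3.91 ± 0.51). For MHC class II genes, camera gave adjusted p = 1.37e-05 (adjusted p = 0.15 with an estimated correlation). For pan-reactive astrocyte genes, 9 of 10 measured members rose (9 adjusted over the list alone), with Gfap (5.26 ± 0.25) and Vim (4.71 ± 0.35). Camera on the pan-reactive astrocyte list gave adjusted p = 6.27e-18 (adjusted p = 0.058 with an estimated correlation). The matrix genes Lox (4.82 ± 0.41) and Col3a1 (2.92 ± 0.38) rose, and 9 of 11 measured members rose (9 adjusted over the list alone). Camera on the fibroblast and matrix list gave adjusted p = 3.55e-06 (adjusted p = 0.16 with an estimated correlation). Growth and trophic factors held Igf1 (1.82 ± 0.21) and Tgfb1 (2.40 ± 0.29), and 5 of 11 measured members rose and 1 fell (5 and 1 adjusted over the list alone). The growth factor list had a camera adjusted p = 0.0286 (adjusted p = 0.15 with an estimated correlation). In the interferon list 8 of 10 measured members rose (8 adjusted over the list alone), with Bst2 (2.82 ± 0.43) and Ifit1 (2.47 ± 0.40). The interferon list had a camera adjusted p = 8.39e-05 (adjusted p = 0.21 with an estimated correlation).

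Nearly the whole striatal projection neuron list fell in GS at 15 d: 1 of 18 measured members rose and 17 fell (1 and 17 adjusted over the list alone), with Adora2a (-0.98 ± 0.086), Rasd2 (-0.96 ± 0.091) and Pde10a (-0.82 ± 0.094). For projection neuron genes, camera gave adjusted p = 5.47e-13 (adjusted p = 0.15 with an estimated correlation). Of the general neuronal genes, 11 of 14 measured members fell (12 adjusted over the list alone), with Nefm (-1.05 ± 0.12) and Rbfox3 (-0.61 ± 0.097). Camera on the general neuronal list gave adjusted p = 1.77e-06 (adjusted p = 0.16 with an estimated correlation). Fgf16 (-2.52 ± 0.35), Gpr139 (-2.16 ± 0.21), Gjd3 (-2.10 ± 0.38) and the axon guidance receptor gene Robo3 (-1.96 ± 0.22) were among the genes that fell most. Lrrk2-associated genes held Lrrk1 (1.67 ± 0.27) and Ctsl (1.54 ± 0.20), and 7 of 14 measured members rose (8 adjusted over the list alone). For Rab and lysosome genes, camera gave adjusted p = 0.0177 (adjusted p = 0.24 with an estimated correlation). Cilia genes Ccdc153 (3.93 ± 0.75) and Foxj1 (2.60 ± 0.27) rose, and in the choroid plexus and ependyma list 5 of 11 measured members rose (5 adjusted over the list alone). Camera on the choroid plexus and ependyma list gave adjusted p = 0.0272 (adjusted p = 0.46 with an estimated correlation). In total 6972 genes changed in edgeR, 3652 up and 3320 down, of which 1500 rose and 357 fell by at least 2-fold. Without GS 15 d replicate 2 that number was 4546, and the 34 genes named here that passed did so without each of the 16 libraries.

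**Figure D2:**
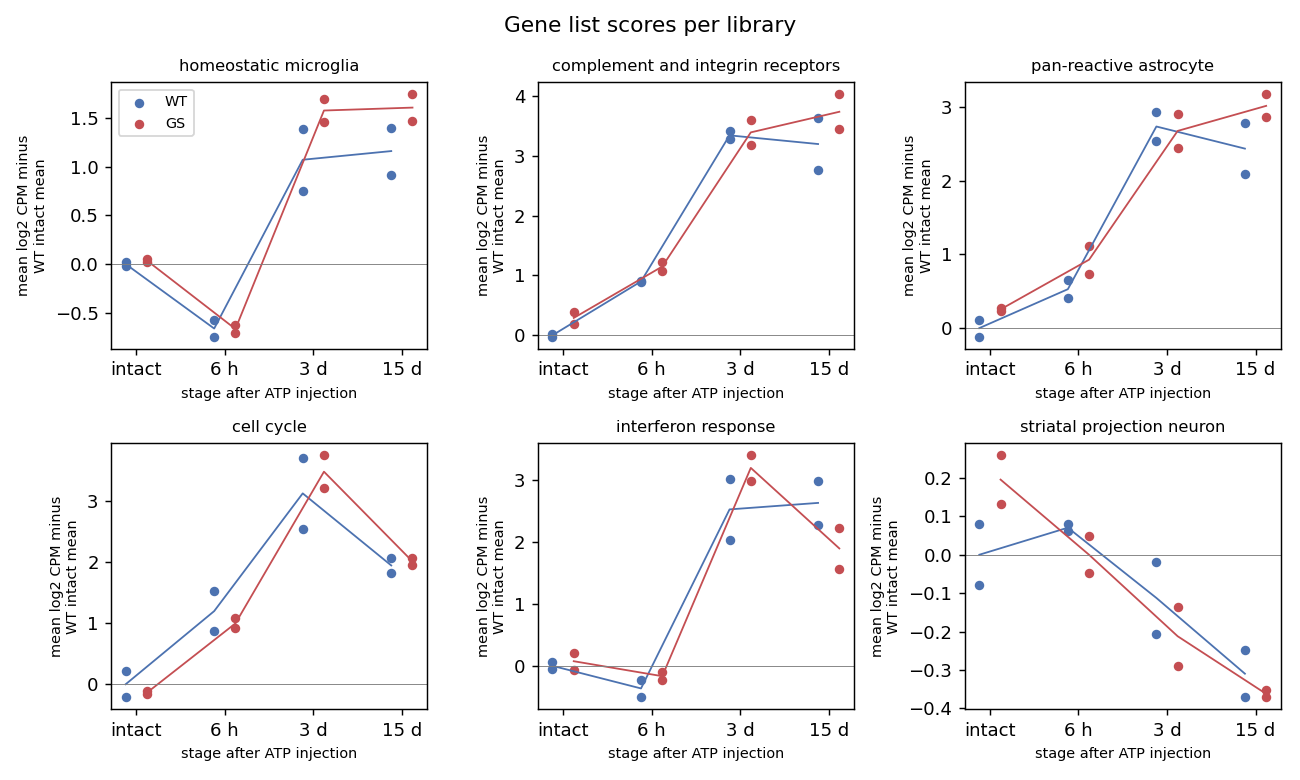
Mean log2 CPM over the members of 6 gene lists in each library (points), less the mean of the WT intact libraries, with lines through group means (n = 2), for WT (blue) and GS (red) by stage. Homeostatic microglia lie below the WT intact mean at 6 h and above it at 3 d and 15 d in all injected libraries of both genotypes.

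WT and GS responses moved largely the same way, and the comparison shares no library between genotypes. Across all tested genes their log2 fold changes correlated at a Pearson r of 0.535 at 6 h, 0.81 at 3 d and 0.853 at 15 d (Spearman 0.479, 0.702 and 0.771), with genes not independent replicates. Of the genes changed in either genotype, 489 changed in the same direction in both at 6 h, 3691 at 3 d and 4058 at 15 d, and 1, 4 and 1 in opposite directions. Independent lists of these sizes would share 35.6 higher and 18.6 lower genes at 6 h, against 314 and 175 seen. The matching values were 516 and 392 against 2193 and 1498 at 3 d, and 519 and 372 against 2386 and 1672 at 15 d.

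The clearest difference between genotypes was a lower level of Psme4, which encodes a nuclear activator of the proteasome (NCBI Gene 103554, mm10 chromosome 11, positions 30771775 to 30881150). Psme4 stood at 26 ± 1.49 CPM in GS against 53.5 ± 3.79 CPM in WT intact striatum, 33.2 ± 0.113 against 58.7 ± 0.187 CPM at 6 h, 33.8 ± 2.45 against 65.5 ± 0.32 CPM at 3 d and 30.9 ± 0.272 against 58.7 ± 0.389 CPM at 15 d (SD, n = 2 each). It was the single gene that passed at all 4 stages in edgeR, with -1.04 ± 0.071 (adjusted p = 9.63e-06), -0.82 ± 0.071 (adjusted p = 0.000192), -0.95 ± 0.071 (adjusted p = 2.69e-05) and -0.93 ± 0.071 (adjusted p = 4.21e-05). Averaged over stages Psme4 differed by -0.94 ± 0.035 (edgeR adjusted p = 2.53e-09), every GS library (25.0 to 35.5 CPM) lying below every WT library (50.8 to 65.7 CPM). Its call at 3 d was lost when only the groups compared were fitted (-0.95, adjusted p = 0.115).

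**Figure D3:**
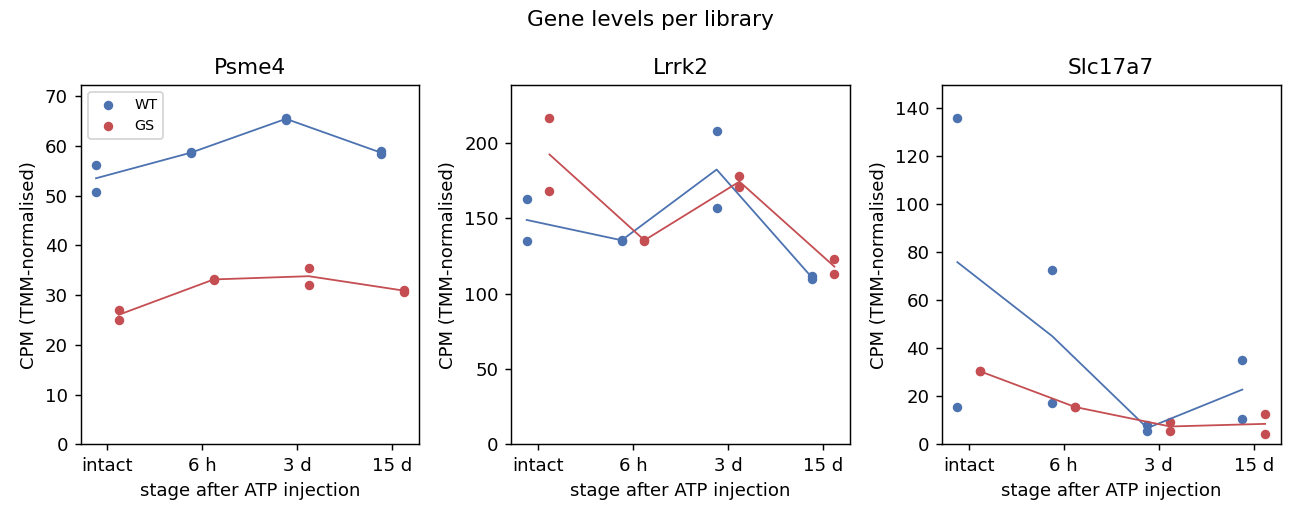
TMM-normalised CPM of Psme4, Lrrk2 and Slc17a7 in each library (points) by stage, with lines through group means (n = 2), for WT (blue) and GS (red). Psme4 lies between 50.8 and 65.7 CPM in WT and between 25.0 and 35.5 CPM in GS, and Slc17a7 is far apart between the WT intact replicates.

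In intact striatum the lymphocyte transcription repressor gene Bach2 stood at 16.8 ± 2.89 CPM in GS and 8.73 ± 1.24 CPM in WT (0.94 ± 0.13, edgeR adjusted p = 0.0314), and Ldlrad4, an inhibitor of TGF-beta signalling, at 120 ± 5.17 and 88 ± 0.624 CPM (0.45 ± 0.064, edgeR adjusted p = 0.0314; SD, n = 2 each). With Psme4 these were all 3 genes that passed, 2 higher and 1 lower in GS. Striatal projection neuron genes lay slightly higher in GS as a list (median 0.19, 17 of 18 members positive), and endothelial genes likewise (median 0.29, 9 of 11 members positive), with no member of either passing over all genes (5 and 3 higher adjusted over the list alone). Camera on the projection neuron list gave adjusted p = 8.23e-10 (adjusted p = 0.67 with an estimated correlation). For endothelium genes, camera gave adjusted p = 0.00054 (adjusted p = 0.95 with an estimated correlation). The endothelial median was 0.45 without WT intact replicate 1 and 0.15 without WT intact replicate 2. Slc17a7 was at 136 and 15.6 CPM in the WT and 30.3 and 30.4 CPM in the GS intact libraries, and Ttr at 359 CPM in GS intact replicate 1. At an unadjusted p under 0.05 there were 2056 genes, and DESeq2 called 165, limma-voom 6. Bach2 lost its call without 10 of the 16 libraries (edgeR adjusted p up to 0.677, without WT intact replicate 1) and Ldlrad4 without 9 (adjusted p up to 0.604, without WT intact replicate 1), both lost it with only the intact groups fitted (adjusted p = 0.211 and 0.176), and 26 genes passed without GS intact replicate 1. Both were lost as well without the 3 WT libraries highest in cortical markers (edgeR adjusted p = 0.647 and 0.526).

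At 6 h Psme4 alone passed between genotypes, with 1285 genes at an unadjusted p under 0.05. DESeq2 called 57 genes, and edgeR called 62 with only these groups fitted and 7 without GS 6 h replicate 2. Sex-linked genes were lower in GS as a list (median -0.68, 0 of 4 members positive), 0 of 4 passing over all genes and 3 adjusted over the list alone. The sex-linked list had a camera adjusted p = 6.37e-05 (adjusted p = 0.87 with an estimated correlation). The Y-linked genes Ddx3y (49.4 and 18.1 CPM) and Kdm5d (20.8 and 7.63 CPM) were low in GS 6 h replicate 2. Pan-reactive astrocyte genes were higher in GS as a list (median 0.29, 10 of 10 members positive), with 0 members passing over all genes and 0 adjusted over the list alone. The pan-reactive astrocyte list had a camera adjusted p = 0.0208 (adjusted p = 0.87 with an estimated correlation). Without GS 6 h replicate 1 the astrocyte median was 0.15, and the sex-linked median was -1.54 without GS 6 h replicate 1 and -0.15 without GS 6 h replicate 2.

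At 3 d the connexin gene Gjc3, found in oligodendrocytes, stood at 61.5 ± 3.92 CPM in GS and 40.3 ± 3.41 CPM in WT (SD, n = 2 each; 0.61 ± 0.087, edgeR adjusted p = 0.0497), and passed together with Psme4. Myelin and oligodendrocyte genes were higher in GS as a list (median 0.30, 14 of 14 members positive), as were homeostatic microglia (median 0.42, 11 of 11 members positive) and interferon genes (median 0.50, 10 of 10 members positive). For myelin genes, camera gave adjusted p = 3.26e-13 (adjusted p = 0.28 with an estimated correlation). The homeostatic microglia list had a camera adjusted p = 2.21e-11 (adjusted p = 0.28 with an estimated correlation). For interferon genes, camera gave adjusted p = 1.41e-05 (adjusted p = 0.52 with an estimated correlation). Immediate early genes (median -0.46, 3 of 15 members positive) and erythrocyte genes (median -1.69, 0 of 4 members positive) were lower in GS. For immediate early genes, camera gave adjusted p = 1.14e-05 (adjusted p = 0.52 with an estimated correlation). Camera on the erythrocyte list gave adjusted p = 5.67e-06 (adjusted p = 0.28 with an estimated correlation). The interferon median was 0.03, 1.07 and 0.33 without WT 3 d replicate 1, WT 3 d replicate 2 and GS 3 d replicate 2. For homeostatic microglia it was 0.18 without WT 3 d replicate 1 and 0.79 without WT 3 d replicate 2, for myelin genes 0.47 without WT 3 d replicate 2, and for immediate early genes -0.83 without GS 3 d replicate 1 and -0.18 without GS 3 d replicate 2. Of all 14 lists called by camera at 3 d, 13 had a median that moved by over 1.5 times or turned sign without a single library. No member of these 5 lists passed over all genes, and adjusted over the list alone 10 myelin, 6 microglia and 3 interferon genes were higher and 0 immediate early and 4 erythrocyte genes lower. At an unadjusted p under 0.05 there were 1552 genes, and DESeq2 called 17 and limma-voom 1. The number was 0 with only these groups fitted, 74 without WT 3 d replicate 2 and 142 without GS 3 d replicate 1, and Gjc3 kept its call without WT 3 d replicate 2, GS 3 d replicate 1 or either WT 15 d library and lost it without each of the other 12 (edgeR adjusted p up to 0.996). Gjc3 lost it too with limma-voom (adjusted p = 0.0801) and in edgeR with no low-count filter (adjusted p = 0.0856), the cortical covariate (adjusted p = 0.0948) or without the 3 WT libraries (adjusted p = 0.14).

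At 15 d Psme4 alone passed, with 915 genes at an unadjusted p under 0.05 and 3 called by DESeq2. EdgeR called 4 with only these groups fitted. Phagocytic microglia (median 0.46, 14 of 14 members positive), complement and integrin receptor (median 0.55, 9 of 10 members positive) and pan-reactive astrocyte genes (median 0.45, 10 of 10 members positive) were higher in GS as lists. For phagocytic microglia genes, camera gave adjusted p = 6.5e-10 (adjusted p = 0.24 with an estimated correlation). The complement and integrin list had a camera adjusted p = 2.84e-08 (adjusted p = 0.24 with an estimated correlation). For pan-reactive astrocyte genes, camera gave adjusted p = 2.33e-07 (adjusted p = 0.24 with an estimated correlation). Interferon genes were lower in GS (median -0.79, 1 of 10 members positive) with a median of -0.34 without WT 15 d replicate 2 and -0.47 without GS 15 d replicate 1, and cortical excitatory neuron genes were lower too (median -1.16, 0 of 9 members positive), with Slc17a7 at 35 and 10.5 CPM in WT and 12.5 and 4.47 CPM in GS. Camera on the interferon list gave adjusted p = 6.5e-10 (adjusted p = 0.24 with an estimated correlation). For cortical neuron genes, camera gave adjusted p = 0.00186 (adjusted p = 0.31 with an estimated correlation). Over all genes 0 members of these lists passed, and adjusted over the list alone 0 phagocytic, 4 complement and 0 astrocyte genes were higher and 4 interferon and 0 cortical genes lower. Without WT 15 d replicate 1, WT 15 d replicate 2 or GS 15 d replicate 2 the median was 0.14, 0.85 or 0.22 for phagocytic microglia, 0.21, 1.01 or 0.28 for complement, 0.14, 0.80 or 0.23 for pan-reactive astrocyte and -0.09, -1.76 or -0.69 for cortical genes, the last being -1.83 without GS 15 d replicate 1. Of all 16 lists called by camera at 15 d, 15 moved by over 1.5 times or turned sign in this way.

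Averaged over the 4 stages, 2 genes passed in edgeR, Psme4 and Gm13456 (mm10 chromosome 2, positions 40555685 to 40557432), a predicted pseudogene named here after its values were seen. Gm13456 was higher in GS by 0.28 on the log2 scale (edgeR adjusted p = 0.0104), and whether it shares reads with a parent gene was not tested. DESeq2 called 75 genes, and 1857 had an unadjusted p under 0.05. The call of Gm13456 was lost without GS 6 h replicate 2 (adjusted p = 0.0512) or GS 15 d replicate 1 (adjusted p = 0.0599), and with the cortical marker score as a covariate (adjusted p = 0.0565) or without the 3 WT libraries highest in cortical markers (adjusted p = 0.219). Homeostatic microglia genes (median 0.23, 11 of 11 members positive) and infiltrating monocyte markers (median 0.54, 4 of 4 members positive) were higher in GS as lists, and cortical excitatory neuron genes, which mark the dissection, were lower (median -0.85, 0 of 9 members positive). For homeostatic microglia genes, camera gave adjusted p = 1.36e-08 (adjusted p = 0.48 with an estimated correlation). For monocyte and macrophage genes, camera gave adjusted p = 6.64e-07 (adjusted p = 0.084 with an estimated correlation). Camera on the cortical neuron list gave adjusted p = 0.00161 (adjusted p = 0.54 with an estimated correlation). Of these lists 0 members passed over all genes, and adjusted over the list alone 0 microglia and 4 monocyte genes were higher and 0 cortical genes lower. The cortical median was -0.44, -0.45 and -0.50 without WT intact replicate 1, WT 6 h replicate 2 and WT 15 d replicate 1.

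Whether the injury response differed between genotypes was tested by the interaction of genotype and stage. At 6 h the actin nucleator gene Cobl went from 85.3 ± 5.69 to 69.6 ± 3.62 CPM in WT and from 119 ± 6.92 to 57.9 ± 3.26 CPM in GS (SD, n = 2 each; difference -0.74 ± 0.11, edgeR adjusted p = 0.0463). Fam163b went from 86.5 ± 4.8 to 120 ± 1.78 CPM in WT and from 105 ± 5.18 to 92.5 ± 1.88 CPM in GS (difference -0.66 ± 0.093, edgeR adjusted p = 0.0463). No gene passed at 3 d or 15 d, or in the joint test of the 3 times, in edgeR, with 1866, 1028 and 1471 genes at an unadjusted p under 0.05. DESeq2 called 132 genes at 6 h, 66 at 3 d, 20 at 15 d and 114 in the joint test. Striatal projection neuron genes responded more negatively in GS at 6 h (median -0.32, 1 of 18 members positive), 3 d (median -0.32, 1 of 18 members positive) and 15 d (median -0.25, 1 of 18 members positive), the contrasts sharing the intact libraries in which this list lay higher in GS. The camera values for projection neuron genes were adjusted p = 3.55e-10, 3.6e-10 and 1.18e-11 in that order (adjusted p = 0.98, 0.47 and 0.75 with an estimated correlation). Cobl and Fam163b kept their calls without GS intact replicate 1, when 19 genes passed, or either WT 3 d library, and lost them without each of the other 13 (edgeR adjusted p up to 0.406). Both calls were lost with limma-voom (adjusted p = 0.0525 and 0.0525), and in edgeR with the stricter low-count filter (adjusted p = 0.0501 and 0.0501), only the groups compared (adjusted p = 0.0605 and 0.0601), the cortical covariate (adjusted p = 0.0633 and 0.0633) or without the 3 WT libraries (adjusted p = 0.293 and 0.333). At 3 d 28 genes passed without WT 3 d replicate 2 and 46 without GS 3 d replicate 1, and in the joint test 11 without WT 3 d replicate 2.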

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

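The interaction tests of genotype and stage were fixed before the data were examined, and the tests of explanations for the interferon and Y-linked patterns, the list medians without single libraries and the comparison with intact striatum were chosen after those results were seen. Differences in response are the GS change minus the WT change on the log2 scale, and none held in every check. Cobl (-0.745) and Fam163b (-0.66) passed per gene at 6 h, and both lost their calls with limma-voom, the stricter low-count filter, only the groups compared, the cortical covariate or without the 3 WT libraries. All other differences are list medians called by camera at a preset correlation, and all of these calls were lost with an estimated correlation (lowest adjusted p = 0.98 at 6 h, 0.47 at 3 d and 0.75 at 15 d).

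At 6 h the median of the GS response minus the WT response was positive for immediate early genes (0.17) and negative for striatal projection neuron (-0.316), endothelium (-0.456) and sex-linked genes (-0.555). At 3 d homeostatic microglia (0.42), phagocytic microglia (0.329), myelin (0.354), oligodendrocyte precursor (0.223), fibroblast (0.441), cell cycle (0.436) and interferon genes (0.33) had positive medians of this difference. For myelin genes the response itself had a median of -0.254 in WT and 0.14 in GS, and for oligodendrocyte precursor genes -0.145 and 0.173. Striatal projection neuron (-0.324), general neuronal (-0.142), heat shock (-0.361) and erythrocyte genes (-2.14) had negative medians of it at 3 d, the erythrocyte response being 1.35 in WT and -0.726 in GS. At 15 d homeostatic microglia (0.36), phagocytic microglia (0.495), pan-reactive astrocyte (0.328), oligodendrocyte precursor (0.207), fibroblast (0.359), complement (0.356) and growth factor genes (0.189) had positive medians of it. Striatal projection neuron (-0.246), choroid plexus and ependyma (-0.233), endothelium (-0.221) and interferon genes (-0.63) had negative medians of it at 15 d, the choroid plexus list with a mean of -0.931 and Ttr at 359 CPM in GS intact replicate 1.

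Single libraries carried many of these medians: 2 of 4 lists called at 6 h, 8 of 11 at 3 d and 10 of 11 at 15 d moved by over 1.5 times or turned sign when a library was left out, and the projection neuron list did so at no time. At 6 h the median was -0.00919 for immediate early genes without GS intact replicate 1 and -0.0266 for sex-linked genes without GS 6 h replicate 2. Without WT 3 d replicate 1 it was 0.157 for homeostatic microglia, 0.0198 for phagocytic microglia, 0.0542 for oligodendrocyte precursor, -0.0266 for cell cycle, 0.0271 for interferon and 0.0135 for general neuronal genes. For fibroblast genes it was -0.0192 without GS 3 d replicate 2, and for myelin genes 0.533 without WT 3 d replicate 2. Without WT 15 d replicate 1 the 15 d medians were 0.198 for homeostatic microglia, 0.0623 for phagocytic microglia, 0.0875 for pan-reactive astrocyte, -0.00485 for oligodendrocyte precursor, 0.142 for fibroblast, 0.0319 for complement and 0.102 for growth factor genes. Without WT 15 d replicate 2 they were 0.0214 for endothelium and -0.298 for interferon genes, and without GS intact replicate 1 0.0645 for choroid plexus genes. For some lists the genotypes differed more in intact striatum, whose libraries these contrasts share, than after injury. In GS minus WT these were projection neuron (0.188 intact against -0.0982, -0.0769 and -0.0539 at 6 h, 3 d and 15 d), endothelium (0.295 against -0.0459 at 6 h and 0.118 at 15 d), heat shock (0.235 against -0.0506 at 3 d) and immediate early genes (-0.215 against 0.159 at 6 h).

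Interferon genes were higher in GS than in WT at 3 d (list median 0.502) and lower at 15 d (-0.786). No member passed, and both camera calls were lost with an estimated correlation. Homeostatic microglia genes were higher in GS at both stages (0.42 and 0.434, or 0.175 and 0.209 without WT replicate 1 of the stage). More immune cells may account for 3 d. At 15 d, fewer immune cells of other types remain possible. Single libraries moved each interferon difference, to 0.0339, 1.07 and 0.333 without WT 3 d replicate 1, WT 3 d replicate 2 and GS 3 d replicate 2, and to -0.343 and -0.472 without WT 15 d replicate 2 and GS 15 d replicate 1. Spread between the libraries of a group is therefore a candidate explanation at both stages. A difference in interferon signalling between the genotypes stays open and untested.

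The lower sex-linked list in GS at 6 h came with GS 6 h replicate 2, where Ddx3y, Kdm5d, Uty and Eif2s3y stood at 0.366 to 0.399 of their level in replicate 1. In raw counts these genes had ratios of 0.335 to 0.365, against a median of 0.915 and a 5th percentile of 0.816 over the 7934 other tested genes at least as abundant, which argues against scaling or depth. RNA from a female animal in part of this library could give lower Y-linked levels, and the 4 X-linked partner genes, with a median ratio of 1.02 (0.982 to 1.03), cannot be told apart from equal levels, since their ratio between replicates elsewhere reached 1.07 to 1.25. Across the other libraries Eif2s3y was also lower at 6 h (47.6, 36.5 and 36.4 CPM) than in intact striatum (60.4 to 72.9 CPM). Kdm5d (21.5, 23.1 and 20.8 against 29.3 to 33.2 CPM) and Uty (24, 21.5 and 19 against 30.6 to 35.1 CPM) were lower as well. A lower level at 6 h was thus not particular to that library for these 3 genes. At 3 d all 4 Y-linked genes lay below every intact library in both genotypes, Ddx3y at 30.9 to 43.7 against 49.6 to 51.1 CPM. Of the X-linked partners, Ddx3x, Kdm5c and Eif2s3x lay above every intact library at 3 d, and Kdm6a overlapped. No biological explanation was tested.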

How the results depend on the processing

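The fits with the cortical marker score as a covariate and without the 3 WT libraries highest in cortical markers were chosen after seeing the data, and all other alternatives were fixed beforehand. With DESeq2 the count of changed genes moved to 1457 for WT injury at 6 h, to 165, 57, 17 and 3 for genotype in intact striatum, at 6 h, 3 d and 15 d, to 132, 66, 20 and 114 for the interaction at 6 h, 3 d, 15 d and any time, and to 75 for genotype averaged over stages. A log2 fold change of at least 1, a stricter threshold by construction, left 155, 1417 and 1361 genes for WT and 556, 1612 and 1857 for GS injury, 1, 0, 0 and 0 for genotype at the 4 stages, 0 for the interaction at 6 h and 0 for the average. Fitting only the groups of a contrast, which leaves fewer samples, gave 1482 and 3216 for WT injury at 6 h and 3 d, 1, 62, 0 and 4 for genotype at the 4 stages and 1 for the interaction at 6 h, and was not run for the average or the joint test, which use all groups. Genotype in intact striatum gave 5 genes with RLE size factors, 6 with limma-voom and 6 with the stricter filter, genotype at 3 d 1 with limma-voom and 1 with no filter, and the interaction at 6 h 0 with limma-voom and 0 with the stricter filter. With the cortical covariate the counts were 2467 for WT injury at 3 d, 1 and 2 for genotype at 3 d and 15 d, and 0 for the interaction at 6 h. Without the 3 WT libraries they were 4, 2178 and 2281 for WT injury, 1, 4, 1 and 3 for genotype at the 4 stages and 0 for the interaction at 6 h. The fit without the 3 WT libraries had 1 library each for WT intact, 6 h and 15 d, so its counts cannot be assigned to cortical tissue. Where the construction does not show it, the cause was not tested.

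Replicate numbers did not pair the samples: over 28 pairs of groups the correlation of same-numbered deviations ran from -0.092 to 0.16, and 3 were over 0.1. With the replicate block the counts were 5 for genotype in intact striatum, 2 at 6 h, 0 for the interaction at 6 h, where Cobl and Fam163b lost their calls (edgeR adjusted p = 0.0628 and 0.0628), and 5 for the average. It left 187 list calls against 189 of 434, those lost being immediate early genes for the interaction at 6 h (camera adjusted p = 0.0505) and growth and trophic factors for the interaction at 15 d (camera adjusted p = 0.053), while an estimated correlation left 8. Left-out libraries gave ranges of 63 to 1073, 2414 to 5497 and 2264 to 5161 for WT injury, 866 to 2959, 3928 to 6758 and 4546 to 7277 for GS injury, 1 to 26, 1 to 7, 1 to 142 and 1 to 2 for genotype at the 4 stages, 0 to 19, 0 to 46, 0 to 0 and 0 to 11 for the interaction and 1 to 5 for the average, a group left with 1 library being taken to vary like the others. Leaving out the 264 tested genes within 10 Mb of Lrrk2 left the averaged count at 2. This could not remove Psme4 or Gm13456, which lie on other chromosomes, so it is no check of those 2 calls. Lrrk2 changed sign, and the cause was not tested: for genotype at 6 h with DESeq2 (-0.00014), no filter (-0.000571), the covariate (-0.00461) and left-out libraries (-0.00793 to 0.00872), and in ranges over left-out libraries for WT injury at 6 h (-0.266 to 0.00581), GS injury at 3 d (-0.317 to 0.0545) and genotype at 3 d (-0.255 to 0.156). Of 216 values for named genes, 216 kept direction and side of the threshold with RLE size factors, 26 lost their call with limma-voom, 9 with the cortical covariate, 44 without the 3 WT libraries and, by construction, 43 at the fold threshold. Over left-out libraries 3255 of 3456 kept both, 195 lost their call, 1 gained it and 5 changed sign. At 2 libraries per group the median standard error of a log2 fold change was 0.136, and 0.192 for an interaction, which limits what these counts can show of small differences.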

Other observations

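Among the other cell types of the striatum, a part of the homeostatic astrocyte genes rose at 3 d: 6 of 13 measured members in WT and 7 in GS (7 and 7 adjusted over the list alone). The camera values for homeostatic astrocyte genes were adjusted p = 0.0173 and 0.0255 in that order (adjusted p = 0.35 and 0.37 with an estimated correlation). Of the oligodendrocyte precursor genes, 0 of 10 measured members passed (0 higher and 4 lower adjusted over the list alone) in WT and 3 fell (5 adjusted over the list alone, where 2 rose) in GS at 6 h. The camera values for oligodendrocyte precursor genes were adjusted p = 0.0057 and 0.0808 in that order (adjusted p = 0.57 and 0.71 with an estimated correlation). At 15 d 4 of 10 measured members rose in WT and 7 in GS (5 and 7 adjusted over the list alone). The camera values for oligodendrocyte precursor genes were adjusted p = 0.0658 and 0.00889 in that order (adjusted p = 0.47 and 0.36 with an estimated correlation). Few neutrophil markers were measured, and at 3 d 1 of 3 measured members rose (2 adjusted over the list alone) in WT. The neutrophil list had a camera adjusted p = 0.0299 (adjusted p = 0.12 with an estimated correlation). For T and B lymphocyte markers at 15 d, 1 of 3 measured members rose and 1 fell (1 and 1 adjusted over the list alone) in WT, and likewise in GS. The camera values for lymphocyte genes were adjusted p = 0.915 and 0.647 in that order (adjusted p = 0.92 and 0.67 with an estimated correlation). Cell cycle genes were still higher at 15 d, when 10 of 14 measured members rose in WT and 12 in GS (11 and 13 adjusted over the list alone). The camera values for cell cycle genes were adjusted p = 2.38e-08 and 5.68e-07 in that order (adjusted p = 0.18 and 0.21 with an estimated correlation). Of the mouse substrain markers, 0 rose and 0 fell in edgeR between genotypes averaged over stages (of 7 measured). The substrain list had a camera adjusted p = 0.97 (adjusted p = 0.99 with an estimated correlation). That contrast held 1857 genes at an unadjusted p under 0.05 and 75 called by DESeq2.

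The tests of Psme4 in this part were chosen after its result was seen, apart from the count over reassigned genotypes. Of 60 reassignments of genotype within stages drawn from 648 possible, the real one included, 2 gave at least the 2 genes that passed averaged over stages, and the highest other gave 4, a share under 0.05 among those drawn, though another reassignment gave more genes than the real one and the Gm13456 call was lost without single libraries, so chance is not firmly excluded for the count. The averaged log2 fold change of Psme4 came no nearer to 0 than -0.913 over 25 settings, left-out libraries included, which argues against scaling, filtering or a single library. Its averaged GS to WT ratio was 0.523 (95% interval 0.497 to 0.551), which holds 0.5, as do the intervals in intact striatum, at 3 d and at 15 d, while that at 6 h (0.509 to 0.628) leaves it out, so a copy of the gene that is not expressed cannot be told apart from another loss of about this size, and an effect of the LRRK2 change stays open and untested. Within 3 Mb, 5 of 44 other tested genes (11.4%) had an unadjusted p under 0.05 against 9.87% of the remaining genes (exact binomial p = 0.618) and 0 passed in edgeR, so a stretch of another strain's chromosome cannot be told apart from a difference in this gene alone, for too few neighbours.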
